A study of Homo sapiens with 4 samples.

How the data were processed

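RNA from 4 samples of TOV-112D cells was sequenced, 2 labelled BSA and 2 labelled PA, with a dose of 200 µM and a time of 24 h per the labels. Libraries were made with a NEBNext Ultra RNA kit per the labels' protocols. Per the submitters' processing notes the build was hg38 and the tools were HISAT2 (an aligner), StringTie (a transcript assembler and quantifier) and SAMtools, with no versions. The annotation release, the counting settings and the use of strand are not given in the sources used here.

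The deposited table held raw read counts per gene, per the file headers, as whole numbers with a different total in each library. It also held FPKM values by the authors (read counts scaled to gene length and library total), per the file headers. Counts divided by FPKM gave the same gene length in all 4 libraries, with a median ratio of 1.0 over 6808 genes. All columns of values were assigned to a sample by name. Of 28973 genes, 1399 had no count in any library, and 25 symbols stood on more than 1 row. Gene identifiers, symbols and coordinates were those of the table.

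Groups were taken from the sample titles, which match the treatment labels. Total counts were 28657038 and 31695944 for BSA replicates 1 and 2 and 29662410 and 23722074 for PA replicates 1 and 2. At these depths a gene at 1 CPM rests on 23.7 to 31.7 counts per library, so low genes carry large counting error. The BSA and the PA replicates differed by more than sampling noise (median chi-square over genes 38.93 and 2.45, against 0.455 for sampling noise alone), so no library was a copy of another.

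Counts were tested with edgeR 4.0.16 in R 4.3.3, using TMM normalisation, the filterByExpr filter and the quasi-likelihood F test with Benjamini-Hochberg adjustment at 0.05. The filter left 17449 genes. Standard errors are the log2 fold change divided by the square root of F. Levels are TMM-normalised CPM. The fit had no replicate block. In all, 32 gene lists with 935 genes, 905 of them in the table, were tested with camera in limma 3.58.1, with a preset inter-gene correlation of 0.01. Of these, camera called 15, 10 up and 5 down. With an estimated correlation it called 0. That version of camera also draws its p from the residual degrees of freedom (libraries beyond those needed for the group means). With 4 libraries these are so few that small values were hardly attainable, whatever the correlation. The fry test, which asks whether a list's genes move one way on balance, called 16. Those included the oxidation, palmitoylation, apoptosis and endothelial lists, which camera did not call (fry adjusted p = 0.00872, 0.046, 0.0272 and 0.00872). They left out the uptake, glycolysis and ribosomal protein lists, which camera called (fry adjusted p = 0.142, 0.102 and 0.181). The procedure was tested on simulated data with the spread of all 4 libraries over 17067 genes. It recovered 59.5% of genes with a log2 change of 2 and 98% of those with a log2 change of 4, with 11 unchanged genes called. That simulation draws noise independently for each gene, and its recovery does not carry over to the real libraries, where 0 genes passed although ZDHHC15, LTF and FGFR2 had log2 fold changes of 9.69, 7.09 and 4.66.

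The comparisons, the alternatives, the lists and the rule for named genes were fixed before the data were examined. That rule took the 8 largest rises and 8 largest falls among genes with an adjusted p under 0.05, a mean of at least 1 CPM and groups that do not overlap. It also took up to 4 called members of each called list, up to 3 called members of lists of other cell types or RNA quality, and SPTLC2 and ZDHHC15 always. No gene passed (0 under the part on largest changes), so the rule named only SPTLC2 and ZDHHC15. All other genes were named by a rule chosen after the values were seen, which used an unadjusted p under 0.001 for the largest changes and an adjusted p over the list alone for list members. A few further genes (RSAD2, GDF15, TNFRSF10B, MT1X and those in the closing section) were also named after their values were seen. Some genes that these rules would name are not reported here. Members of multigene families and genes with pseudogenes, such as the IFITM and ribosomal protein genes, may share reads, and overlapping or antisense genes cannot be told apart if strand was not used.

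The alternatives were RLE and upper-quartile factors, no filter, a filter of 1 CPM in 2 libraries, DESeq2 1.42.0, limma-voom, a replicate block, leaving out each library, and limma on log2(FPKM + 1) or log2(FPKM + 0.1). An alternative added after seeing the data removed a loess trend (span 0.3) over GC content and log2 length of each gene's longest GENCODE 29 transcript, which 16596 of the tested genes (95.1%) had. KEGG pathways from the deposited annotation were also tested after seeing the data. Figures were drawn with matplotlib 3.10.9.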

Results

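Per the labels, RNA sequencing compared TOV-112D cells, an established human ovarian cancer line, under palmitic acid with TOV-112D cells under bovine serum albumin (BSA). Palmitic acid is a saturated fatty acid that is usually given to cells bound to albumin. The labels give 200 µM for 24 h, and the stated purpose was to learn how palmitic acid affects the function of ovarian cancer cells. Each group held 2 libraries, labelled BSA and PA. The table held 28973 genes, of which 17511 were protein coding and 11443 were long noncoding RNAs. Total counts were 28657038 and 31695944 in BSA replicates 1 and 2, and 29662410 and 23722074 in PA replicates 1 and 2. Nothing in the labels says that the libraries came from separate cultures, so p-values measure only the spread between these libraries, which may be technical.

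The labels of the PA libraries were in conflict. Title and treatment say palmitic acid, the description speaks of a knockdown of SPTLC2, and the treatment protocol also mentions cells carrying a short hairpin against ZDHHC15. ZDHHC15, a palmitoyltransferase gene (ENSG00000102383, hg38 chromosome X, 75368427 to 75523502, minus strand), was the gene with the largest difference. Its counts were 291 and 225 in the BSA libraries and 190083 and 167798 in the libraries labelled PA. It took 0.6408% of all counts in PA replicate 1 (95% Wilson interval 0.638% to 0.6437%) and 0.7073% in PA replicate 2 (0.704% to 0.7107%), against 0.001015% (0.0009053% to 0.001139%) and 0.0007099% (0.000623% to 0.0008089%) in the BSA libraries. By count it ranked 4 and 2 among all genes in the libraries labelled PA. These intervals cover counting error only. Its normalised level was 6917 ± 538 CPM (read counts scaled to library size; SD, n = 2) in PA and 8.398 ± 1.9 in BSA, a log2 fold change of 9.69 ± 0.45 (SE), with an edgeR adjusted p of 0.0544. It missed the threshold also with RLE factors, upper-quartile factors and a filter of 1 CPM in 2 libraries, and passed in every other alternative run, with log2 fold changes from 8.78 to 9.99.

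SPTLC2, which encodes a subunit of serine palmitoyltransferase, the enzyme that starts sphingolipid synthesis, was not lower in the libraries labelled PA (ENSG00000100596, hg38 chromosome 14, 77505997 to 77616637, minus strand). Its counts were 1524 and 1080 in BSA and 2194 and 1740 in PA. The log2 fold change was 0.83 ± 0.28 (SE), and it did not pass the test (edgeR adjusted p = 0.175). Over the alternatives it ranged from 0.58 (without BSA replicate 2) to 1.18 (without BSA replicate 1), and it passed in both of these and with a GC and length trend removed (0.94). Neither gene therefore had the level that a knockdown in the libraries labelled PA would give. The groups below follow the title and treatment labels, and each direction is drawn from libraries labelled PA whose other labels these 2 genes contradict.

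**Figure D1:**
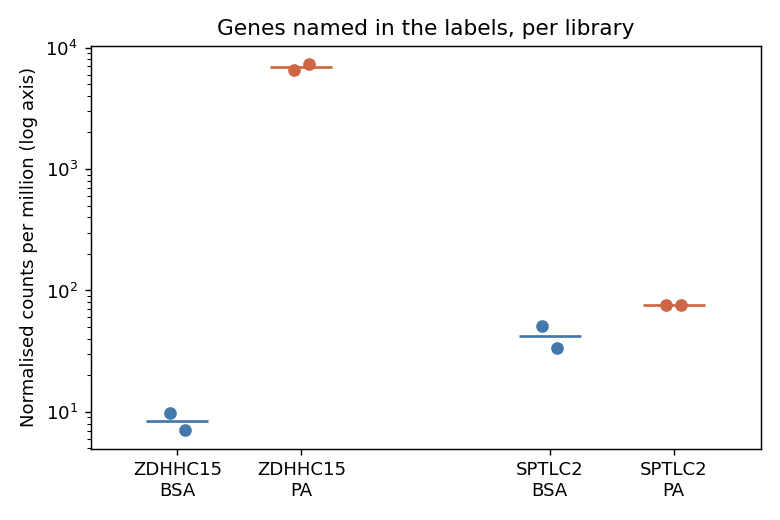
Normalised CPM on a log axis for ZDHHC15 and SPTLC2. Points are single libraries and horizontal lines are group means (n = 2). ZDHHC15 was at 9.74 and 7.056 CPM in the BSA libraries and at 6537 and 7298 CPM in the libraries labelled PA.

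The BSA libraries differed from each other far more than the libraries labelled PA did. Across genes, the SD of the log2 ratio between replicates was 1.00 for BSA and 0.41 for PA. The BSA ratio followed the GC content of the transcripts. With the tested genes in 10 bins of GC content, the median log2 ratio of BSA replicate 2 over replicate 1 was -1.45 in the lowest bin and 0.39 in the highest. The corresponding medians for PA were -0.05 and 0.06. The mean of the PA libraries over BSA replicate 1 also followed GC content (Spearman correlation 0.48, median -1.29 in the lowest bin). Over BSA replicate 2 it did so little (-0.08, median 0.12 in the lowest bin). In log2 CPM, BSA replicate 2 correlated at 0.94 with BSA replicate 1, and at 0.945 and 0.939 with PA replicates 1 and 2. Mitochondrial genes held 1.88% of counts in BSA replicate 2 and 3.75%, 4.56% and 3.7% in BSA replicate 1, PA replicate 1 and PA replicate 2.

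**Figure D2:**
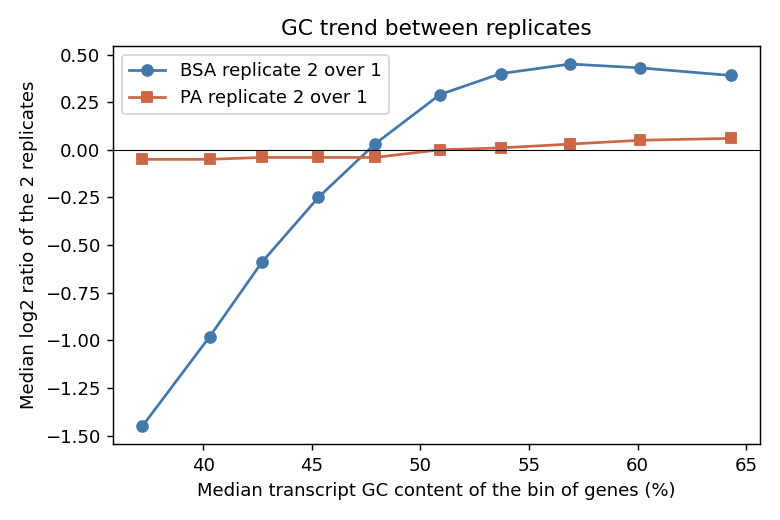
Median log2 ratio of the replicates of each group, for 10 bins of the tested genes by transcript GC content (x axis, percent). The BSA ratio ran from -1.45 in the lowest bin to 0.45 in the bin around 56.9% GC, and the PA ratio stayed between -0.05 and 0.06.

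Over all 17449 genes tested, edgeR's quasi-likelihood test called 0 genes at an adjusted p under 0.05 between the libraries labelled PA and BSA, and the smallest adjusted p was 0.0544. At an unadjusted p under 0.05 there were 4241 genes, 2281 higher and 1960 lower in PA, where chance alone would give 872. The higher share of 53.8% at that threshold was 44.6% without a filter, 47.1% with DESeq2 and 49.4% with upper-quartile factors, so the direction of this majority was not stable. At an unadjusted p under 0.001 there were 245, of which 219 were higher. DESeq2 called 1768 genes, 1022 higher and 746 lower, and 1684 of those were among the 4241. limma-voom called 1 gene, ZDHHC15, as did limma on the deposited FPKM values. With a trend over GC content and transcript length removed, an alternative added after seeing the data, edgeR called 1349 genes, 915 higher and 434 lower, and 1029 of them were also called by DESeq2. Without BSA replicate 1 edgeR called 8842 genes, 4671 higher and 4171 lower, and without BSA replicate 2 it called 10467, 4984 higher and 5483 lower, in fits that take the spread from the PA libraries alone. Without PA replicate 1 it called 16 and without PA replicate 2 it called 9. The groups did not overlap for 10120 genes, 58% of those tested, where chance gives 33.3%. Both chance values, 872 and 33.3%, assume groups that vary alike, but the SD between replicates was 1.00 for BSA and 0.41 for PA. Unequal spread alone can raise the share without overlap, and genes that follow GC content shift together. The excess over either value is therefore no measure of how many genes changed. An exact two-sided permutation test of 2 against 2 libraries cannot give a p below 0.333. The median log2 fold change of all genes was -0.12. Because no gene passed over all genes tested, members of the gene lists fixed before the data were examined are counted below as passing or not when adjusted over the list alone (edgeR), and 0 members of any list passed over all genes. These member counts depend strongly on the BSA libraries, so the counts without BSA replicate 1 and without BSA replicate 2 are given for most lists. They come from fits that take the spread from the PA libraries alone, over 18443 and 18275 genes tested. Large parts of all genes passed in those fits, as given above. Such a count is therefore not by itself a sign of a change particular to that list. Where a list median moved by over 1.5 times or changed sign in any of 12 alternatives, its lowest and highest values over them are given.

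Genes of the cholesterol list were higher in the libraries labelled PA. Of 26 members tested, 18 were higher and 0 lower when adjusted over the list alone, with a median log2 fold change of 1.75. DHCR7, the enzyme of the last step to cholesterol, stood at 44.31 ± 7.49 CPM in BSA and 395.4 ± 48.3 in PA (SD, n = 2), 8.92-fold higher (log2 fold change 3.16 ± 0.25 SE). INSIG1, a sterol-regulated brake on this pathway, was 5.94-fold higher (2.57 ± 0.28). Higher and lower members were 23 and 2 without BSA replicate 1, and 20 and 3 without BSA replicate 2. camera called the list (adjusted p = 1.06e-09), but its adjusted p was 0.259 with an estimated correlation. Here and for the lists and pathways below, the few residual degrees of freedom left that second value little room to be small.

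Fatty acid synthesis and desaturation moved the same way. Of 24 members 8 were higher and 0 lower when adjusted over the list alone (median log2 fold change 0.55). SCD, which introduces a double bond into saturated fatty acids, went from 418.2 ± 76.6 CPM in BSA to 3129 ± 57.8 in PA (SD, n = 2; log2 fold change 2.90 ± 0.29 SE). ACSS2, which makes acetyl-CoA, was 5.95-fold higher, the fatty acid synthase gene FASN 4.14-fold, and the regulator SREBF1 3.14-fold. The camera adjusted p was 0.000457, and 0.259 with an estimated correlation. For fatty acid uptake and activation 4 of 20 members were higher when adjusted over the list alone, SLC27A4, ACSL1, MFSD2A and ACSL3 (median 0.71; camera adjusted p = 0.00593, and adjusted p = 0.423 with an estimated correlation). Among 24 genes of lipid droplets and triglycerides 3 were higher, the lipase genes LIPE (5.78-fold) and MGLL (2.3-fold) and LPIN1, which makes diacylglycerol (3.18-fold), with a list median of 0.58 (camera adjusted p = 0.00492, and adjusted p = 0.289 with an estimated correlation). The uptake median ran from 0.56 (GC and length trend removed) to 1.08 (without BSA replicate 1). The triglyceride median ran from 0.29 (without PA replicate 2) to 0.61 (without BSA replicate 2), and was 0.34 without a filter, with DESeq2 and with the trend removed. Higher members of the synthesis, uptake and triglyceride lists numbered 18, 14 and 14 without BSA replicate 1 (1, 0 and 3 lower), and 14, 9 and 14 without BSA replicate 2 (4, 6 and 4 lower).

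Fatty acid oxidation and PPAR targets were not called as a list by camera, though fry called them (adjusted p = 0.00872). None of the 33 members passed when adjusted over the list alone (0 higher, 0 lower; median 0.32; camera adjusted p = 0.0936), against 18 higher and 4 lower without BSA replicate 1 and 15 and 7 without BSA replicate 2. The KEGG pathway of PPAR signaling, tested after the data were seen, was called up (52 genes, camera adjusted p = 0.00468, and adjusted p = 0.557 with an estimated correlation), with SCD and SLC27A4 among its genes of smallest p. In the sphingolipid list 6 of 36 members were higher and 2 lower (median 0.32; camera adjusted p = 0.121). This median was highest without BSA replicate 1 (0.61), with 21 higher and 9 lower, and lowest without BSA replicate 2 (0.26), with 18 and 12, and it was 0.56 with the trend removed. The KEGG sphingolipid metabolism pathway was called up (46 genes, camera adjusted p = 0.0134, and adjusted p = 0.57 with an estimated correlation). The acid sphingomyelinase gene SMPD1 was 4.39-fold higher, ORMDL3, a regulator of serine palmitoyltransferase, 3.12-fold and the ceramidase gene ACER2 4.05-fold, while SGPP2, a sphingosine-1-phosphate phosphatase gene, was at 3.223 ± 0.676 CPM in BSA and 0.2989 ± 0.131 in PA (SD, n = 2). Of 32 palmitoylation enzymes 3 were higher, ZDHHC15, ZDHHC24 (2.56-fold) and ZDHHC9 (2.03-fold), with a median of 0.04 and a camera adjusted p of 0.0936. There were 17 higher and 2 lower without BSA replicate 1, and without BSA replicate 2 there were 14 and 11. The palmitoylation median ran from 0.01 (upper-quartile factors) to 0.37 (trend removed).

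NF-kB target and inflammatory genes were higher in the libraries labelled PA. Of 25 members 16 were higher and 0 lower when adjusted over the list alone (median log2 fold change 1.59). The macrophage growth factor gene CSF1 went from 11.49 ± 0.387 to 181.7 ± 2.26 CPM (SD, n = 2; log2 fold change 3.98 ± 0.22 SE). IL6, a cytokine gene, went from 17.26 ± 1.45 to 140.9 ± 29.7 CPM (3.03 ± 0.27), and TRAF1, an adaptor of TNF receptors, was 9.83-fold higher. TNF itself was low, at 5 and 6 counts in BSA and 93 and 110 in PA. Leaving out BSA replicate 1 gave 23 higher and 0 lower, and leaving out BSA replicate 2 gave 20 and 1. For this list camera gave an adjusted p of 4.94e-10, and 0.259 with an estimated correlation. The KEGG pathway of NF-kappa B signaling was not called (76 genes, median 0.09, camera adjusted p = 0.122).

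Interferon response genes were lower. Of 37 members 24 were lower and 1, RSAD2, was higher when adjusted over the list alone (median log2 fold change -1.36). XAF1, an interferon-induced gene linked to apoptosis, stood at 51.18 ± 5.49 CPM in BSA and 5.13 ± 0.673 in PA (SD, n = 2; log2 fold change -3.32 ± 0.3 SE). OAS2, a sensor of double-stranded RNA, had a log2 fold change of -2.41 ± 0.22, IFIT3 of -1.77 ± 0.24, and IFITM1 of -2.02 ± 0.24, though reads of the similar IFITM genes may be shared. The fit without BSA replicate 1 had 29 lower and 1 higher, and that without BSA replicate 2 had 29 and 4. Tested with camera, the list had an adjusted p of 8.61e-09, and 0.259 with an estimated correlation. Against each BSA library alone, the median of this list was -1.11 for replicate 1 and -1.15 for replicate 2.

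Endoplasmic reticulum chaperone genes, targets of ATF6 and XBP1, were higher in the libraries labelled PA. Of 30 members 9 were higher and 0 lower when adjusted over the list alone (median log2 fold change 0.67). HSPA5, the main chaperone of this compartment, went from 632 ± 213 to 6878 ± 46.3 CPM (SD, n = 2; 3.44 ± 0.39 SE), and PDIA6, a disulfide isomerase gene, was 4.07-fold higher. DNAJC3 was 2.21-fold higher and UGGT1 2.19-fold. The counts were 20 higher and 3 lower without BSA replicate 1, and 22 and 3 without BSA replicate 2. The camera adjusted p was 1.34e-05, and 0.259 with an estimated correlation. Between the BSA libraries the chaperone median of replicate 2 over replicate 1 was 0.11, and 0.79 with the GC and length trend removed. That is close in size to the difference of PA from BSA with the trend removed (0.87). Against each BSA library alone, without trend removal, the PA median was 0.94 for replicate 1 and 0.86 for replicate 2. The ATF4 branch was not called, with 2 of 39 members higher, GDF15 and TNFRSF10B (camera adjusted p = 0.695). Its median was -0.16, its mean 0.01 and its camera direction up. The BSA libraries differed in the ATF4 list too, whose median log2 fold change for PA was 0.35 against BSA replicate 1 and -0.39 against BSA replicate 2. Its median was -0.37 without BSA replicate 1 (the lowest) and 0.36 without BSA replicate 2 (the highest). Of 25 heat shock genes 3 were higher, SERPINH1, HSPB1 and CRYAB, while the median was -0.34 and the camera direction up (adjusted p = 0.803). That median ran from -0.36 (filter of 1 CPM) to 0.11 (without BSA replicate 1), and was 0.01 with the trend removed, with 8 higher and 3 lower without BSA replicate 1 and 11 and 12 without BSA replicate 2.

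Genes of DNA replication were lower. Of 39 members 6 were lower and 0 higher when adjusted over the list alone (median log2 fold change -0.89). PCNA, the replication clamp gene, stood at 204.9 ± 9.94 CPM in BSA and 77.27 ± 7.1 in PA (SD, n = 2; -1.41 ± 0.2 SE), and RRM2, a subunit of ribonucleotide reductase, at 184.6 ± 48.4 and 60.37 ± 0.612 CPM (-1.61 ± 0.26). The uracil glycosylase gene UNG had a log2 fold change of -1.45. Copies of PCNA elsewhere in the genome make its counts uncertain. With BSA replicate 1 left out 30 members were lower and 1 higher, and with BSA replicate 2 left out 27 and 2. The list's camera adjusted p was 5.46e-06, and 0.259 with an estimated correlation. The mitosis list was not called, with 0 of 35 members passing (median -0.13; camera direction up, adjusted p = 0.907), against 11 higher and 2 lower without BSA replicate 1 and 13 and 17 without BSA replicate 2. The mitosis median ran from -0.15 (filter of 1 CPM) to 0.22 (without BSA replicate 1), and was 0.08 with the trend removed. Ribosomal protein genes all had negative log2 fold changes, 39 of 39, with a median of -0.65, but 0 passed when adjusted over the list alone. All 39 passed as lower without BSA replicate 1 (median -0.85, the lowest), and 24 did without BSA replicate 2 (-0.3, the highest). camera called this list (adjusted p = 3.26e-06; adjusted p = 0.566 with an estimated correlation). Its median was -0.32 against BSA replicate 1 and -0.88 against BSA replicate 2, and reads shared with the many ribosomal pseudogenes make these counts uncertain.

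Among p53 targets 6 of 27 members were higher and 0 lower when adjusted over the list alone (median 0.49; camera adjusted p = 0.00123, and adjusted p = 0.259 with an estimated correlation). BTG2, an antiproliferative gene, was 4.45-fold higher, the decoy receptor gene TNFRSF10C 5.8-fold, the kinase gene PLK2 2.65-fold and PHLDA3, an inhibitor of AKT, 3-fold. This became 15 higher and 2 lower without BSA replicate 1, and 18 and 5 without BSA replicate 2. The KEGG p53 signaling pathway was not called (70 genes, 28 with a positive log2 fold change, median -0.2, camera adjusted p = 0.919). The apoptosis list had 0 of 33 members past the test (median 0.05; camera adjusted p = 0.371). The antioxidant NRF2 list had 0 of 30 (median -0.18; adjusted p = 0.619). Of 25 ferroptosis and iron genes 3 were higher, HSPB1, LPCAT3 and SAT1 (median 0.02; adjusted p = 0.463). Without BSA replicate 1 the apoptosis, NRF2 and ferroptosis lists had 11, 5 and 10 higher and 6, 15 and 6 lower members, and without BSA replicate 2 they had 14, 9 and 11 higher and 9, 9 and 9 lower. The apoptosis median ran from 0 (no filter and DESeq2) to 0.18 (without BSA replicate 2, limma-voom and the replicate block), and the ferroptosis median from -0.05 (filter of 1 CPM) to 0.19 (without BSA replicate 2). For NRF2 it ran from -0.38 without BSA replicate 1 to 0 without BSA replicate 2.

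Extracellular matrix genes were higher in the libraries labelled PA, 11 of 32 members and 0 lower when adjusted over the list alone (median 0.82). COL4A2 was 5.56-fold higher and COL4A1 4.99-fold, both collagen genes of the basement membrane, and the matricellular genes CCN1 and THBS1 were 5.47-fold and 4.24-fold higher. Members higher and lower were 22 and 1 without BSA replicate 1, and 20 and 4 without BSA replicate 2. For this list camera gave an adjusted p of 5.46e-06, and 0.317 with an estimated correlation. In the autophagy and lysosome list 7 of 35 members were higher and 0 lower (median 0.3). NPC1, which moves cholesterol out of lysosomes, was 5.67-fold higher, the cathepsin genes CTSD and CTSB 5.31-fold and 3.1-fold, and the lysosomal membrane gene LAMP1 3.02-fold. Here 18 were higher and 8 lower without BSA replicate 1, and 21 and 6 without BSA replicate 2. The camera adjusted p was 0.00596, and 0.359 with an estimated correlation. Immediate early genes went both ways, 11 of 35 higher and 5 lower (median 0.27; camera adjusted p = 0.198), with 14 and 11 without BSA replicate 1 (median 0.1, the lowest), 19 and 10 without BSA replicate 2 (0.5, the highest), and a median of 0.17 with the trend removed. NR4A2 was 5.07-fold higher and NR4A1 3.34-fold, while EGR1 had a log2 fold change of -2.49 ± 0.28 (SE).

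Glycolysis and hypoxia genes were lower, 6 of 35 members against 1 higher when adjusted over the list alone (median -0.56). ANKRD37, BNIP3 and NDRG1, genes induced in hypoxia, had log2 fold changes of -2.71, -1.25 and -1.4, while P4HA2, a collagen hydroxylase gene, was 2.79-fold higher. The median ran from -0.63 (without PA replicate 2) to -0.35 (without PA replicate 1), and 22 members were lower and 11 higher without BSA replicate 1, and 19 and 6 without BSA replicate 2. By camera the adjusted p of this list was 0.0224, and 0.554 with an estimated correlation. The KEGG pathway of glycolysis and gluconeogenesis was not called (46 genes, median -0.1, camera adjusted p = 0.872), nor was that of HIF-1 signaling (80 genes, median -0.02, camera direction up, adjusted p = 0.489). For nuclear genes of oxidative phosphorylation 0 of 42 members passed (median -0.33; camera adjusted p = 0.0224, and adjusted p = 0.317 with an estimated correlation). That call was lost with the GC and length trend removed (median -0.21; adjusted p = 0.0874), and the KEGG oxidative phosphorylation pathway was not called (123 genes, median -0.22, camera adjusted p = 0.364). Of the list's members 20 were lower and 0 higher without BSA replicate 1, and 16 and 4 without BSA replicate 2. Its median ran from -0.36 (upper-quartile factors) to -0.21 (without BSA replicate 2 and with the trend removed). Mitochondrially encoded genes had 0 of 13 past the test (median 0.32; adjusted p = 0.18), and of 5 metallothionein and zinc genes 1 was lower, MT1X (median -0.88; adjusted p = 0.316). Without BSA replicate 1 the mitochondrial list had 11 higher and 1 lower (median 0.59), and without BSA replicate 2 it had 6 and 5 (median 0.14), the ends of its range, while its median was 0.52 with the trend removed. The metallothionein median ran from -1.11 (without PA replicate 1) to -0.29 (trend removed), and the fits without BSA replicate 1 and without BSA replicate 2 each had 1 higher and 3 lower.

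**Figure D3:**
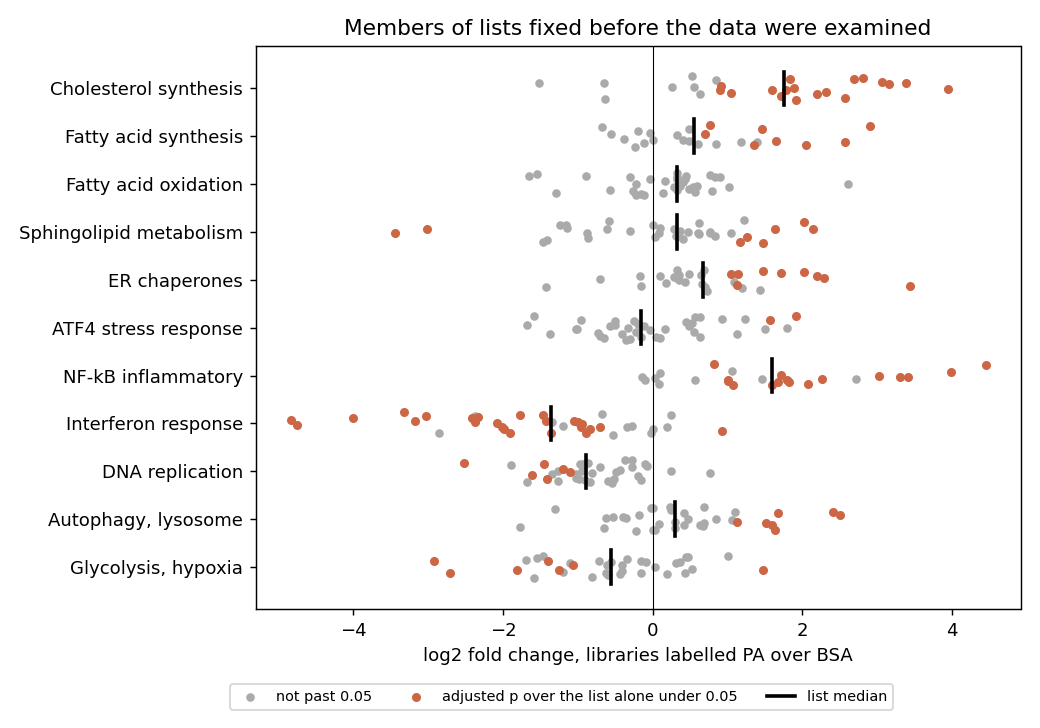
Log2 fold changes of the libraries labelled PA over BSA (x axis) for members of 11 gene lists. Each point is a gene, coloured points had an adjusted p under 0.05 over the list alone, and black bars are list medians. Medians were 1.75 for cholesterol synthesis, 1.59 for NF-kB genes and -1.36 for the interferon response.

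Lists of other cell types and of RNA quality were measured beside these. Ovarian epithelial tumour markers were higher, 5 of 20 members when adjusted over the list alone (median 0.21; camera adjusted p = 0.0196, and adjusted p = 0.317 with an estimated correlation), among them CLDN4 (4.49-fold), MSLN (2.8-fold) and MUC1 (2.86-fold). That call was lost with the GC and length trend removed (adjusted p = 0.103), with a list median of 0.22 while that of all genes went from -0.12 to -0.03, and log2 fold changes of 1.85, 1.42 and 1.43 for CLDN4, MSLN and MUC1 (2.17, 1.48 and 1.52 before). With BSA replicate 1 left out 8 members were higher and 4 lower, and with BSA replicate 2 left out 11 and 2. The median ran from 0.17 (no filter and DESeq2) to 0.47 (filter of 1 CPM). Of 6 endothelial, erythroid and adipocyte markers 2 were higher from low counts, CDH5 with 9 counts over both BSA libraries and 94 over PA, and PECAM1 with 3 and 37 (14.6-fold, 95% counting interval 4.63 to 74.2). The list's camera adjusted p was 0.0837, and its median of 1.49 changed sign, to -0.84 with DESeq2 (the lowest) and -0.72 without a filter, and was highest with limma-voom (1.76). Its counts were 2 higher and 0 lower without BSA replicate 1, and 3 and 0 without BSA replicate 2, and those of the immune markers below were 1 and 1, and 2 and 1. Of 5 immune markers 1 was higher, CSF1R (3.91-fold), and 1 was lower when adjusted over the list alone (median 0.38, from 0.01 without BSA replicate 1 to 0.48 with limma-voom; camera adjusted p = 0.753), and 0 of 6 fibroblast and mesothelial markers passed (median -0.26; camera direction up, adjusted p = 0.996). Replication-dependent histone genes had 0 of 23 members past the test (adjusted p = 0.225), with a median of 0.93 against BSA replicate 1 and -0.36 against BSA replicate 2. Nuclear noncoding RNAs had 0 of 6 (median -0.42; camera direction down, adjusted p = 0.996). The medians of the last 3 lists changed sign among the alternatives. The histone median ran from -0.27 (without BSA replicate 1) to 0.99 (without BSA replicate 2), the nuclear noncoding RNA median from -0.44 (filter of 1 CPM) to 0.32 (without BSA replicate 1) and the fibroblast median from -0.42 (without PA replicate 1) to 0.46 (without BSA replicate 1). In that order, higher and lower members were 1 and 5, 2 and 1, and 2 and 2 without BSA replicate 1, and 10 and 2, 3 and 3, and 2 and 4 without BSA replicate 2.

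Beyond the lists, the genes with the largest differences at an unadjusted p under 0.001 also held several with low levels in BSA. After ZDHHC15 came ATP6V0D2, a subunit of the lysosomal proton pump (0 and 2 counts in BSA, 252 and 164 in PA, a ratio of 247 with a 95% counting interval of 67.9 to 2040), and the lactoferrin gene LTF, at 0.1934 ± 0.0369 CPM in BSA and 26.99 ± 2.91 in PA (SD, n = 2). NEURL3 was 56.9-fold higher, SH2D3C 26.9-fold, the growth factor receptor gene FGFR2 25.2-fold, and the kinase gene CAMK2A 22.1-fold. RTP3 had 4 counts over both BSA libraries and 103 over PA (ratio 30.5, interval 11.6 to 114). The genes lower in PA began with the heat shock gene HSPA6, whose counts were 819 and 2607 in BSA and 57 and 56 in PA (log2 fold change -4.63 ± 0.65 SE). PJVK, SGPP2, XAF1, PRSS56 and WFIKKN1 had log2 fold changes of -3.72, -3.44, -3.32, -3.05 and -2.96. The antisense transcripts NARF-AS2 and ID2-AS1 had -3.27 and -3.18, and whether the counting used strand is not given in the sources used here.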

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

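The removal of a GC content and length trend was chosen after the data were seen, and the other alternatives before. The count of 0 genes with edgeR and TMM factors was also 0 with RLE factors, upper-quartile factors and a filter of 1 CPM in 2 libraries. It was 1302 without a filter, 1768 with DESeq2, 1349 with the GC and length trend removed, and 1 with limma-voom and with each of the 3 limma fits to FPKM. Leaving out 1 library gave 9 to 10467 genes. Genes changed at least 2-fold numbered 1299 without a filter, 1766 with DESeq2, 1186 with the trend removed and 1 in the limma fits, and 9 to 5494 with 1 library left out. The highest counts came without a BSA library, where the remaining BSA library is assumed to vary like the PA libraries. Causes of the other moves were not tested. The share of calls that were higher in PA was 64.7% without a filter, 57.8% with DESeq2, 67.8% with the trend removed, 52.8% without BSA replicate 1 and 47.6% without BSA replicate 2, where the majority turned.

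The labels do not say that the replicate numbers pair the libraries. Deviations of same-numbered libraries correlated at 0.008. That cannot show whether they were made together, since the BSA ratio followed GC content (Spearman correlation 0.6) and the PA ratio did so far less (0.14). A replicate block gave 537 genes, 74.9% of them higher and all changed at least 2-fold (537), and 15 lists.

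Of 32 gene lists, 15 were called. An estimated correlation called 0. For the NF-kB, interferon and chaperone lists the estimate was -0.004, -0.012 and -0.017, below the preset 0.01. Their adjusted p still rose to 0.259, which argues against a higher correlation as the reason for these lists. Some called lists had estimates above the preset, such as cholesterol (0.057) and ribosomal proteins (0.688). With an estimated correlation camera also draws its p from the few residual degrees of freedom that 4 libraries leave. Small p-values were then hardly attainable, whatever the correlation, so the 0 calls do not show that correlated genes undid the calls. Other settings called 13 to 16, including 13 with the trend removed. Over 12 settings the sign of the list median held in all 12 for 22 lists. It differed in some for the ATF4, mitosis, apoptosis, NRF2, ferroptosis, heat shock, histone, nuclear noncoding RNA, fibroblast and endothelial lists. For single named genes no setting reversed a direction. Except for SPTLC2 and ZDHHC15, these genes were chosen from the same data for small p, and the largest changes also for groups that do not overlap. A reversal was therefore unlikely from the start. In 736 comparisons of a gene and a setting the gene stayed on its side of the threshold, and in 486 it passed only in the alternative. No gene passed in the main fit, so none could lose a call. Leaving out either BSA library raised the number of list members past the test in most lists, from 0 to 39 and 24 for ribosomal proteins and from 6 to 30 and 27 lower members for DNA replication. Depth limits genes with few BSA counts, such as ATP6V0D2 with 2.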

Other observations

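Tests of the X chromosome region around ZDHHC15 and of the BSA spread after trend removal were chosen before their results were seen, and all other tests here after. KEGG pathways of the deposited annotation gave 69 of 326 called with the preset correlation, 59 up and 10 down in the libraries labelled PA, of which 47 were also called in the same direction with the GC and length trend removed. With an estimated correlation 0 were called, but the few residual degrees of freedom of 4 libraries made any call hardly attainable. The lysosome pathway had the smallest p. Of its 122 genes 54 had an unadjusted p under 0.05, and 50 of those were higher (median log2 fold change 0.62; camera adjusted p = 1.13e-07, and adjusted p = 0.557 with an estimated correlation). Its higher genes included the receptor gene IGF2R (2.43 ± 0.26 SE), the saposin gene PSAP (2.32 ± 0.25), LGMN (1.97 ± 0.21) and the proton pump gene ATP6AP1 (1.85 ± 0.2). The adhesion molecule pathway (72 genes, median 0.87; adjusted p = 2.9e-06, and adjusted p = 0.557 with an estimated correlation) held L1CAM, CD276 and ICAM1 on the higher side. Glycerophospholipid metabolism had 24 genes with an unadjusted p under 0.05, all 24 higher (adjusted p = 7.88e-05, and adjusted p = 0.557 with an estimated correlation).

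Mismatch repair, homologous recombination and DNA replication were among the 10 pathways called down, with medians of -0.6, -0.55 and -0.62 (adjusted p = 0.0248, 0.0134 and 0.00575, and adjusted p = 0.585, 0.585 and 0.557 with an estimated correlation). Pathways with names close to the fixed lists did not always go with them. Steroid biosynthesis, TNF signaling and protein processing in the endoplasmic reticulum were called up (adjusted p = 0.00729, 0.00276 and 0.00537, and adjusted p = 0.578, 0.557 and 0.557 with an estimated correlation). PPAR signaling and sphingolipid metabolism were called up where camera did not call those lists (adjusted p = 0.00468 and 0.0134, and adjusted p = 0.557 and 0.57 with an estimated correlation). NF-kappa B signaling, fatty acid biosynthesis, autophagy, oxidative phosphorylation, glycolysis and p53 signaling were not called where camera called those lists (adjusted p = 0.122, 0.457, 0.268, 0.364, 0.872 and 0.919). RIG-I-like receptor signaling, which leads to interferon, was also not called (median -0.19, adjusted p = 0.752).

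The level of ZDHHC15 in the libraries labelled PA is opposite to what a short hairpin would give. Reads shared with related genes are argued against, since the next ZDHHC gene, ZDHHC5, had at most 0.0337 of the ZDHHC15 count, and so is gain of the surrounding region, since 5 tested genes starting within 1 Mb had a median log2 fold change of -0.88 ± 0.38 (SE). Libraries from another cell line are also argued against, though the bound of 10 genes was set without a profile of another line. Only 1 gene, ATP6V0D2, was at 5 CPM or more in both libraries of 1 label and at 0.1 CPM or less in both of the other, as many as between the BSA replicates (1). An introduced ZDHHC15 construct or a mix-up of labels stays open and cannot be told apart from an effect of palmitic acid, because either goes with the label: ZDHHC15 lay 5.74 log2 units above the next gene with a mean of at least 100 CPM.

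The spread between the BSA libraries had an SD of 1.00 across genes. GC content and length bias as the whole cause is argued against, since the SD fell only to 0.76 with that trend removed, against 0.40 for PA. Sampling noise is argued against, since the SD was 0.63 among 4503 genes with at least 1000 counts in every library (PA 0.15). A difference in the integrated stress response may be part of it. With the trend removed, the ATF4 list median of BSA replicate 2 over replicate 1 was 0.69. That lay at percentile 100 of 10000 matched random lists. Ribosomal protein, histone and chaperone lists also lay at percentile 100 and mitochondrially encoded genes at percentile 0. Further lists lay near the ends, such as NRF2 (99.97), DNA replication (98.83), glycolysis (0.02) and heat shock (0.34). Others did not, such as cholesterol (22.11) and interferon (77.87). Members of a list may vary together, which randomly drawn genes need not, so percentile 100 does not single out the ATF4 list. No biological difference between the BSA cultures is given by the labels.

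The cholesterol, NF-kB and interferon lists gave medians of 1.75, 1.59 and -1.36. GC content and length bias is argued against for each, since the medians were 1.58, 1.46 and -1.37 with the trend removed. A single BSA library as the source is argued against too. Taken as differences of mean log2 CPM, without the fitted model, the medians against both BSA libraries were 1.75, 1.67 and -1.34, against replicate 1 alone 1.66, 1.4 and -1.11, and against replicate 2 alone 1.76, 1.81 and -1.15, so that the smallest ratio of single to both was 0.83. The palmitic acid treatment and the unexplained ZDHHC15 level go with the same label, so a hypothesis that palmitic acid produced these shifts could not be separated from one in which ZDHHC15 did (5.74 log2 units above the next abundant gene).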
